A study of Arabidopsis thaliana with 5 samples.

How the data were processed

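DNA from nuclei of 12-day-old Columbia wild-type seedlings was digested with restriction enzymes, precipitated with the S9.6 antibody and sonicated, and adapters were ligated to single-stranded DNA, which keeps the strand of each read. Of 5 samples, 2 DRIP samples have peak lists that were analysed. The 2 samples treated with RNase H and the 1 input sample were not analysed here. Per the submitters' processing notes, reads were handled with CASAVA, aligned with BWA 0.7.12 to TAIR10, and peaks were called with MACS2. The control library, the parameters and any pooling of replicates are not given in the sources used here. There are 4 peak lists: DRIP replicate 1, DRIP replicate 2, and the w and c lists, both recorded under DRIP replicate 1. The names w and c are used only as names of opposite strands, and which of them carries the RNA was not settled.

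The deposited fold values are the ratio of the pileup at a peak's summit to the local background as computed by MACS2 for the authors, not on a log scale. The deposited -log10 p-value and -log10 q-value columns are those of the authors' MACS2 run. The smallest -log10 q-value in the 4 lists lies between 1.30132 and 1.34408, so every peak passed a q-value of 0.05. Peak lists carry no library totals, so the depth of each sample is unknown and no interval that needs it is given. All peaks lie on the 5 nuclear chromosomes, and no peaks of a list overlap each other.

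Genes came from a RefSeq gene table of TAIR10.1, a later release of the same assembly, with 37887 genes, of which 27432 are nuclear protein-coding genes. Peaks and genes were joined by position. This join was checked by shifting the peaks in steps of 50 bp up to 1000 bp either way in 40 parts (stretches of each chromosome by replicate): the shift that placed most peak bases in protein-coding genes had a median of 0 bp and lay between -50 and 50 bp. Only peak coordinates, counted from 1, are printed. The gene table used gives no transcribed strand, exons or untranslated regions, and no genome sequence was used. The planned comparison of strand-specific peaks with gene orientation and the planned sequence skew of w and c peaks were therefore not run, genes were not divided into exons and introns, and gene ends were named by coordinate in place of start and end.

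Comparisons, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Chosen after the data were seen were the feature classes used in place of exons and untranslated regions, the comparison of lower- with higher-coordinate gene ends, the division of long noncoding RNA genes by overlap with protein-coding genes, and the tests and alternatives that the closing section names as such. Overlaps, genome features and noncoding classes were compared with 1000 random relocations of the peaks within their chromosome (two-sided, smallest possible p 0.0020), with Benjamini-Hochberg adjustment within each list of peaks and a threshold of 0.05. Relocation treats peaks as independent. Each base was given to the first that applied of protein-coding gene, small RNA gene, pseudogene, long noncoding RNA gene, gene flank (1 kb) and intergenic DNA. Pericentromeric regions were set by gene content and not taken from an annotation. On each chromosome they span 2.5 Mb either side of the middle of the 500 kb step with the fewest protein-coding genes. Coverage at gene ends was measured in windows of 500 bp in protein-coding genes of at least 1.5 kb with no other gene within 500 bp, with intervals from 1000 bootstrap draws of 500 kb blocks. The 12 gene lists (circadian clock, flowering time, light-harvesting and Rubisco small subunit, R-loop factor, heat shock, seed storage and oil body, homeotic and developmental regulator, histone, housekeeping, Aux/IAA, NLR and ribosomal protein genes) were compared with 10000 random lists matched on gene length in 20 bins. Ribosomal protein genes were the 67 genes named as such in the table. The list test takes members as independent. Fold values in the text are the highest of the peaks that overlap a gene, and SD is over the 2 replicates.

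Genes named are, by rule, from each list up to 4 members with the highest smaller-of-replicates fold and up to 2 with no DRIP peak in either replicate, the 10 protein-coding genes with the highest smaller-of-replicates fold, the 10 isolated protein-coding genes with the highest w and the 10 with the highest c fold, and up to 3 genes per noncoding class. Replicates are known only from their labels, so the spread between them may be technical.

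The methods were tested on simulated data. Relocated peaks, in lists of 5000, were called different from chance in 1 of 40 overlap tests and 2 of 240 feature tests. The relocation that made them also defines chance, so they cannot show what clustering of real peaks would do. A planted overlap of 60% was estimated at 60.0%. With 5% of peaks moved into pseudogenes, 30 of 40 lists were called. Random lists of 16 genes were called in 20 of 1000 draws. Lists with a raised share were called in 298 (by up to 20 points) and 883 (by up to 40 points) of 1000. The chance of a peak was capped at 100%, so the rise was smaller for long genes, and peaks of replicate 1 alone were used. The snRNA class was called in 0 of 40 null and 40 of 40 planted sets. Intervals at gene ends held a planted log2 ratio of 0 in 90 and of 1 in 93 of 100 draws, so their coverage fell slightly short of 95%. Alternatives covered stricter peaks, each replicate alone, summits, windows, flanks, isolation, matching and local relocation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.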

Results

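R-loops, in which an RNA pairs with one DNA strand and leaves the opposite strand single, were mapped in 12-day-old Arabidopsis thaliana seedlings by DNA:RNA immunoprecipitation (DRIP). DRIP pulls down hybrid-containing DNA with the S9.6 antibody, which binds DNA:RNA hybrids. The series holds 5 samples: 2 DRIP replicates, 2 DRIP samples treated with RNase H, which degrades the RNA of a hybrid, and 1 input. Values were analysed for the 2 DRIP replicates only, so no peak was set against its level after RNase H here. Peak folds are the authors' own and serve to rank peaks within a list. Whether they share a scale across lists is unknown, so folds set side by side for w and c, or averaged over the replicates, are descriptive. DRIP replicate 1 had 47291 peaks over 15.4 Mb and DRIP replicate 2 had 39888 peaks over 13.8 Mb, a mean of 12.3% ± 0.93 of the nuclear genome (SD, n = 2). Peak lists carry no read totals, so the depth of each library is unknown. The median peak was 240 bp wide in replicate 1 and 270 bp in replicate 2. Libraries built on single-stranded DNA also gave one peak list per strand, named w and c by the authors and recorded under DRIP replicate 1. The w list held 34493 peaks over 11.5 Mb and the c list 34069 peaks over 11.5 Mb. All coordinates are those of the TAIR10 genome, and a gene was counted as carrying a peak when at least 1 bp of it was overlapped.

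The first comparison asked how far the R-loop maps of the DRIP replicates coincided. Of 27432 protein-coding genes, 16619 (60.6%) carried a DRIP peak in both replicates and 8562 (31.2%) carried none in either. Outside the comparison of strands, genes are ranked by the smaller of their folds in the DRIP replicates, while the printed value is the mean, so a gene left out can have a higher mean. The protein-coding genes ranked highest in this way were AT2G08986 (mean peak fold 10.8 ± 0.44, SD, n = 2), AT1G64380 (10.4 ± 1.12) and AT3G22150 (9.91 ± 0.43). The AT2G08986 peak lay at chromosome 2, 3625879 to 3626412, in replicate 1. The next 7 genes by this rank, with mean folds from 8.40 to 9.69, were AT5G10340, AT1G36990, AT1G22110, AT2G16586, AT1G21580, AT4G36230 and AT5G14460, and each of these 10 genes carried both a w and a c peak.

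Replicate 2 peaks were nearly all found again: 95.1% of them overlapped a replicate 1 peak, and 79.5% of replicate 1 peaks overlapped a replicate 2 peak. After random relocation of the peaks within their chromosome the shares were 24.9% and 21.3%. Bases shared by both lists made up 0.70 of the bases in either (Jaccard index), against 0.065 after relocation. Both shares and the index exceeded every one of 1000 relocations (two-sided permutation p = 0.0020, the smallest that 1000 relocations can give). The share ranged from 79.2% to 80.0% over the 5 chromosomes for replicate 1 and from 94.6% to 95.3% for replicate 2. Among replicate 1 peaks, 48.2% of those in the lowest quartile of fold were found in replicate 2, and 99.9% of those in the highest quartile. For replicate 2 peaks found in replicate 1 the shares were 85.6% and 99.98%. Nothing in the labels says that the replicates came from separately grown seedlings, so the spread between them may be technical.

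The second comparison asked which parts of the genome the peaks occupied. Protein-coding genes held 66.5% ± 0.28 of DRIP peak bases (SD, n = 2), 1.23-fold ± 0.0052 over relocated peaks. Genes of small structured or regulatory RNAs (tRNA, snoRNA, snRNA, miRNA and rRNA genes) outside protein-coding genes were covered 2.76-fold ± 0.13 over chance. Pseudogenes, which in this gene table include many transposon-derived genes, were covered 1.35-fold ± 0.027 over chance. Bases within 1 kb of a gene held 0.629-fold ± 0.0045 the chance share, and intergenic DNA farther out 0.430-fold ± 0.015. Genes of long noncoding RNAs outside the other classes lay slightly below chance at 0.885-fold ± 0.0048.

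The w and c lists showed the same order of features. Protein-coding genes were at 1.21-fold over chance for w and 1.22-fold for c, pseudogenes at 1.31-fold and 1.29-fold, and intergenic DNA at 0.485-fold and 0.476-fold. Each DRIP replicate passed the relocation test for all 6 features, with Benjamini-Hochberg adjusted permutation p from 0.0024 to 0.0060. Long noncoding RNA genes passed in neither strand list (adjusted permutation p = 0.33 for w and 0.054 for c). With peak summits in place of peak bases the DRIP value for long noncoding RNA genes was 0.971-fold (adjusted permutation p = 0.909; range over the alternatives 0.0020 to 0.909), and without pericentromeric regions intergenic DNA was at 0.194-fold. For peaks in the upper 50% by fold, pseudogenes were no longer separable from chance on either strand (1.04-fold for w and 1.03-fold for c).

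**Figure D1:**
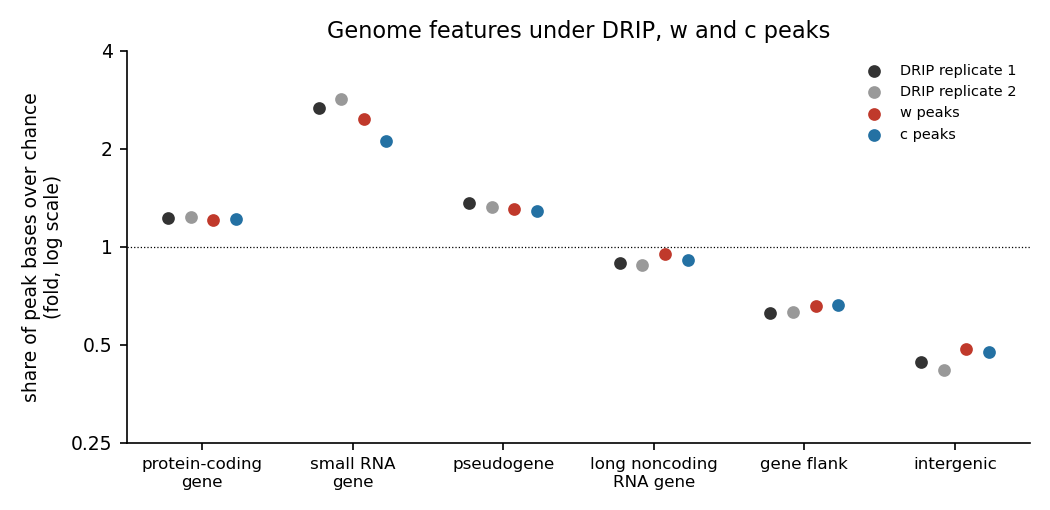
Share of peak bases in each genome feature divided by the mean share after random relocation (fold, log scale), for DRIP replicates 1 and 2 and the w and c lists, 1 point per list, with the dotted line at chance. Small RNA genes sit highest, at 2.76-fold for the DRIP mean, and intergenic DNA lowest, at 0.430-fold.

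Longer protein-coding genes carried DRIP peaks more often. In the shortest quartile of genes 42.7% ± 3.14 carried a peak (SD, n = 2), in the next 62.9% ± 3.8, then 72.8% ± 4.04, and in the longest quartile, of genes above 3030 bp, 80.3% ± 3.91. Gene groups were therefore compared with random lists matched on gene length.

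The third comparison set the 2 strands against each other. Among isolated protein-coding genes, those with no other annotated gene within 500 bp, the highest w folds were at AT5G54400 (w 11.8, c 4.02), GALS2 (w 11.6, c 3.85), AT3G28270 (w 11.3, c 8.00) and WRKY11 (w 11.3, no c peak). GALS2 encodes a galactan synthase of the cell wall and WRKY11 a transcription factor. LSH6, AT3G12970, AT5G23430 and AT3G47610 carried w folds from 10.8 to 11.1 and no c peak, while AT5G19090 and CR88, the chloroplast HSP90, carried w folds of 10.7 and also a c peak. The highest c folds were at RKL1 (c 12.1, w 6.13), a receptor-like kinase gene, AT1G21000 (c 11.8, w 4.57), AT3G28420 (c 11.7, no w peak) and IRX12 (c 11.7, w 3.68), a laccase gene. AT3G28420, the cell wall gene XTH4 (c 11.4), the transcription factor gene WRKY47 (c 11.3) and the arabinogalactan protein gene AGP5 (c 10.8) had no w peak. TCP15, HOG1 and AT3G22150 completed the 10 highest c folds, with w folds of 3.83, 6.63 and 7.78.

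Peaks of opposite strands seldom coincided. The w and c lists shared 587517 bp, 0.529 of the amount after relocation, and 11.2% of w peaks overlapped a c peak against 18.3% after relocation (two-sided permutation p = 0.0020). Of w and c peaks, 61.3% and 61.6% overlapped a peak of DRIP replicate 2, against 21.6% of each after relocation (two-sided permutation p = 0.0020). The shares for replicate 1, under which both strand lists are recorded, were 72.1% and 72.3%, and overlap with it is no independent comparison. Whether replicates were pooled for the strand lists is not given, so the independence of replicate 2 is not known either. Another 8854 w peaks (25.7%) and 8649 c peaks (25.4%) overlapped no DRIP peak of either replicate, and their median folds were lower (3.0 for w and 2.97 for c) than those of peaks found in both replicates (4.86 and 4.89). Of 37612 replicate 1 peaks found again in replicate 2, 44.2% overlapped a w peak only, 43.6% a c peak only, 11.8% both and 0.391% neither. Peaks with both strands made up 8.09% (95% Wilson interval 7.57 to 8.64) of the lowest fold quartile and 20.2% (19.4 to 21) of the highest. Such intervals cover counting error only, and amplified reads without molecular identifiers are not independent molecules. Of all protein-coding genes, 6632 carried a w peak only, 6608 a c peak only, 8429 both and 5763 neither. The share of w peaks overlapped by c was 6.52% for peaks in the upper 50% by fold and 2.62% with a reciprocal overlap of 50%, both below their own chance values.

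**Figure D2:**
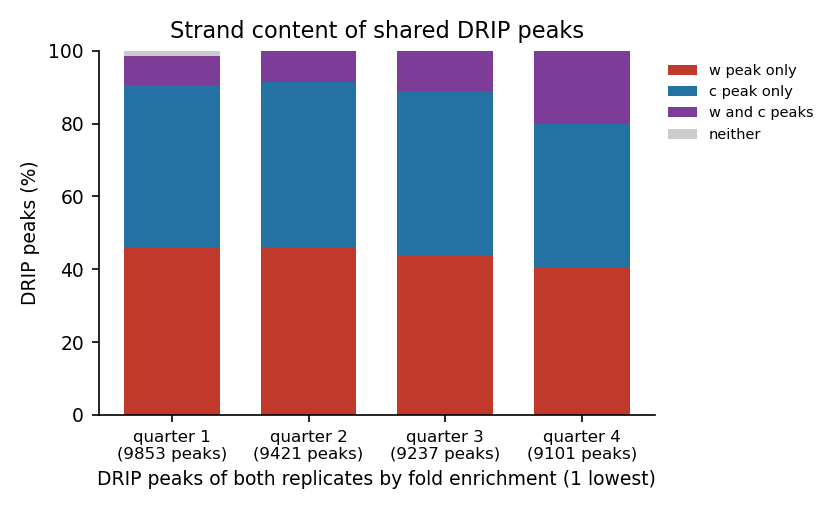
Percent of DRIP replicate 1 peaks found again in replicate 2 that overlap a w peak only, a c peak only, both or neither (stacked bars), by quartile of fold enrichment from lowest to highest. Peaks with both strands make up 8.09% of the lowest quartile and 20.2% of the highest.

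The fourth comparison located the peaks along 4546 isolated protein-coding genes of at least 1.5 kb. The gene table gives no transcribed strand, so the ends are named by coordinate, a comparison chosen after the data were seen. DRIP peaks covered 17.2% ± 1.07 of the first 500 bp inside the lower-coordinate gene end, 17.7% ± 1.18 of the gene middle and 17.0% ± 0.79 of the last 500 bp inside the higher-coordinate end (SD, n = 2). The 500 bp just outside were covered 5.92% ± 0.21 and 6.20% ± 0.15. The log2 ratio of inside to outside coverage was 1.52 in replicate 1 (95% block bootstrap interval 1.44 to 1.61) and 1.47 in replicate 2 (1.39 to 1.56).

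Inside genes the w and c peaks favoured opposite ends. The w peaks covered 7.36% of the lower end and 17.9% of the higher end, a log2 ratio of -1.28 (95% interval -1.42 to -1.15). The c peaks covered 18.1% of the lower end and 7.19% of the higher end, a log2 ratio of 1.33 (1.19 to 1.46). Coverage of the gene middle lay between that of the ends, at 13.1% for w and 13.4% for c. The w ratio was negative and the c ratio positive on each of the 5 chromosomes. Outside the gene ends the asymmetry was smaller, at -0.29 (-0.47 to -0.12) for w and 0.28 (0.12 to 0.45) for c. The DRIP lists showed no such asymmetry, with inside log2 ratios of 0.04 (-0.06 to 0.14) in replicate 1 and 0.00 (-0.10 to 0.11) in replicate 2. Over all protein-coding genes of at least 1.5 kb, isolated or not, the inside to outside log2 ratio was 0.70. The ratio of gene ends to gene middle, -0.05 ± 0.02, was not separable from 0 in the main setting and depended on the settings (0.16 over all genes and -0.18 with 250 bp windows).

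**Figure D3:**
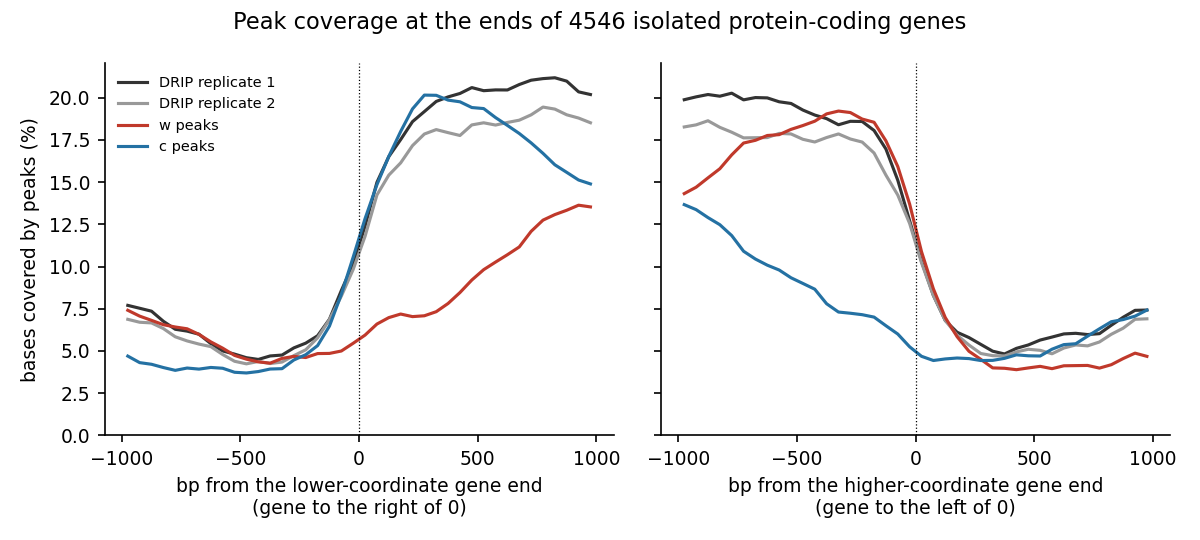
Percent of bases covered by peaks in 50 bp bins from 1000 bp outside to 1000 bp inside the lower-coordinate (left) and higher-coordinate (right) ends of 4546 isolated protein-coding genes, for DRIP replicates 1 and 2, w and c peaks. Coverage by c peaks rises inside the lower end and coverage by w peaks inside the higher end, where they average 18.1% and 17.9% over 500 bp.

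The fifth comparison asked whether gene groups fixed before the data were examined carried R-loop peaks more often than other genes of their length. Heat shock genes, a list of heat shock protein genes and 1 heat shock factor gene, did: 12 of 13 carried a DRIP peak in both replicates, against 51.9% in matched random lists. This result was lost without replicate 1, with summits required inside the gene, without length matching and with 1 kb added on either side. Ranked highest were AT1G53540, a small heat shock protein gene (5.73 ± 0.43, SD, n = 2), HSP70 (5.08 ± 0.31), HSP18.2 (4.87 ± 0.44) and AT1G07400 (4.51 ± 0.036). The 1 member without a peak in both, HSP17.6A, had one in replicate 1 only and is named after its values were seen. The AT1G53540 peak spanned chromosome 1, 19980277 to 19981565, in replicate 1. AT1G53540, HSP18.2 and AT1G07400 carried a w peak and no c peak, and HSP70 a c peak and no w peak.

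Photosynthesis genes carried DRIP peaks in 19 of 24 cases against 56.5% in matched lists, which did not pass after adjustment. The Rubisco small subunit genes RBCS1A (6.51 ± 0.80), RBCS2B (6.43 ± 0.35) and RBCS1B (4.78 ± 0.085) and the photosystem I antenna gene LHCA1 (5.45 ± 0.044) ranked highest by the smaller fold. LHCB6 and Lhca6 had no DRIP peak in either replicate but each had a c peak (folds of 5.31 and 2.81). On the c strand the photosynthesis group passed, with 20 of 24 genes against 50.1% matched, and so did the housekeeping group, with 16 of 17 against 59.4%. Both results were lost with summits required inside the gene and with 1 kb added on either side. On the w strand the counts were 17 of 24 against 49.4% and 15 of 17 against 60.5%. A difference between strands was not detected (exact McNemar test, adjusted p = 1 for both lists). Only 1 housekeeping gene had a w peak alone and 2 a c peak alone, too few for this test to pass. Such differences also depend on how many members lie on each genome strand, and the gene strand was not used. Housekeeping genes carried DRIP peaks in 14 of 17 cases, led by TUA4 (5.98 ± 0.57), an alpha-tubulin gene, ACT8 (5.59 ± 0.12), an actin gene, GAPC1 (4.59 ± 0.16) and PP2AA3 (4.49 ± 0.37).

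Clock genes carried DRIP peaks in 10 of 12 cases. LHY, a morning-phased transcription factor gene, was highest (4.95 ± 0.67, SD, n = 2), ahead of PRR7 (4.39 ± 0.33), PCL1, also known as LUX (4.16 ± 0.042), and TOC1 (3.98 ± 0.19). GI had a c peak (2.96) and no DRIP peak. Flowering time genes were the only group below its matched share, with 12 of 18 against 75.1%. AGL20, also known as SOC1 (3.91 ± 0.23), FRI (3.87 ± 0.099), FPA (3.79 ± 0.056) and VIN3 (3.77 ± 0.13) ranked highest in this group, and the floral repressors MAF1 and AGL31 had no DRIP peak, with a c peak at MAF1 (2.67).

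Developmental regulators carried DRIP peaks in 12 of 16 cases, among them the meristem gene STM (5.84 ± 0.021), the seed maturation regulators ABI3 (5.77 ± 0.38) and FUS3 (4.98 ± 0.18) and the floral identity gene LFY (4.81 ± 0.078). AP1 and PHE1 had no peak in any of the 4 lists. Seed storage genes, 7 of 9 with a peak, included the cruciferin gene CRU3 (5.62 ± 0.72) and the adjacent albumin genes SESA2 (4.47 ± 0.11), SESA3 (4.49 ± 0.37) and SESA4 (4.32 ± 0.43). CRU2 and OLEO2 had no DRIP peak, with a w peak at OLEO2 (2.79).

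Auxin response repressor genes of the Aux/IAA group had peaks in 12 of 16 cases, with IAA7 (5.39 ± 0.38), IAA16 (4.93 ± 0.66), IAA12 (4.33 ± 0.12) and IAA9 (4.13 ± 0.023) ranked highest by the smaller fold and no DRIP peak at SHY2 or ATAUX2-11, which each had a w and a c peak. Immune receptor genes of the NLR type had peaks in 13 of 14 cases, led by RPS6 (5.04 ± 0.37), RPP8 (4.84 ± 0.38), RPP4 (4.77 ± 0.93) and RPS4 (4.18 ± 0.041), with none at AT5G66900. Histone H3 and H4 genes had peaks in 7 of 16 cases, among them AT5G65360 (4.37 ± 0.36), AT5G10390 (4.36 ± 0.60), AT1G07820 (4.23 ± 0.25) and AT3G53730 (3.78 ± 0.12), with no DRIP peak at AT3G45930 or AT4G40030, of which the latter had a c peak. Of the R-loop factors, TOP1ALPHA (4.26 ± 0.071) and TOP1BETA (2.99 ± 0.17), which encode topoisomerase I, AT4G03090 (3.19 ± 0.15) and AT5G51080 (2.64 ± 0.11) were among 5 of 6 with a peak, and AT3G01410 had none. Ribosomal protein genes had peaks in 43 of 67 cases, led by PSRP5 (6.33 ± 0.61), RPS5B (5.85 ± 0.26), PSRP3/1 (5.67 ± 0.24) and RPS10B (5.67 ± 0.0043), and no DRIP peak at RPS15, which had a c peak, or at PFL.

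For DRIP peaks in both replicates, the Benjamini-Hochberg adjusted p over the 12 lists, from 10000 length-matched random lists (two-sided), was 0.046 for heat shock genes and 0.22 for photosynthesis genes, and ranged from 0.40 to 0.96 for the other 10. On the c strand it was 0.014 for photosynthesis genes, 0.020 for housekeeping genes and 0.060 for histone genes, and no list passed on the w strand (0.27 to 1). The test takes list members as independent and does not allow for clustering. Some members are neighbours by locus number, such as RBCS1B, RBCS2B and RBCS3B, TUB2 and TUB3, or HSP17.6II and HSP17.6A. The difference between strands did not pass for any list (exact McNemar test, adjusted p from 0.28 to 1). After adjustment over the lists and noncoding classes, this test could pass only in the photosynthesis, histone and ribosomal protein lists. In every other list too few genes differed between strands, so a lack of difference there decides nothing. The heat shock result was lost in replicate 2 alone (adjusted permutation p = 0.065), with summits required inside the gene (0.11), without length matching (0.16) and with 1 kb added on either side (0.30), and its adjusted permutation p ranged from 0.0024 to 0.30 over the alternatives. The c-strand results for photosynthesis and housekeeping genes were lost with summits required inside the gene (adjusted permutation p = 0.071 for both) and with 1 kb added (0.082 and 0.25). Genes are not replicates, and lists of 16 simulated genes with a peak share raised by up to 20 percentage points were detected in 298 of 1000 draws before adjustment.

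**Figure D4:**
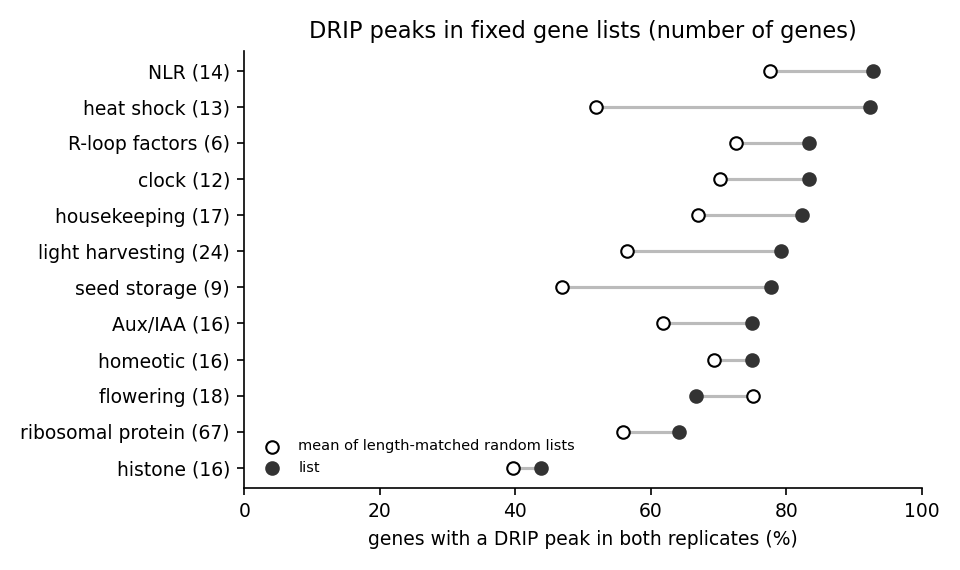
Percent of the genes of each fixed list with a DRIP peak in both replicates (filled points) and the mean percent in length-matched random lists (open points), with the number of genes in parentheses. Heat shock genes, 12 of 13 against 51.9%, are the only list past the threshold after adjustment.

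The sixth comparison concerned noncoding genes. Small nucleolar RNA (snoRNA) genes, whose products guide rRNA modification, stood highest when an overlap of at least 1 bp was counted (the summit rule is given below). Of 287 snoRNA genes, 78.7% ± 2.46 were overlapped by a DRIP peak (SD, n = 2), 5.31-fold ± 0.25 over relocated peaks. Spliceosomal small nuclear RNA (snRNA) genes followed with 57.9% ± 2.59 of 82 genes (3.4-fold ± 0.14) and tRNA genes with 38.4% ± 3.39 of 625 genes (2.77-fold ± 0.026). Long noncoding RNA genes were overlapped 1.12-fold ± 0.011 over chance, in 28.8% ± 2.68 of 3480 genes, but this held only for the 1420 that overlap a protein-coding gene (1.44-fold ± 0.017). The 2060 outside protein-coding genes lay below chance (0.824-fold ± 0.039; two-sided permutation p = 0.0020 in each replicate), as did long noncoding RNA bases outside the other classes (0.885-fold). MicroRNA genes were not above chance, with 14.1% ± 1.3 of 326 genes (0.829-fold ± 0.015).

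Among snRNA genes, U6-26 (7.36 ± 0.076, SD, n = 2) lay under a DRIP peak at chromosome 3, 4561050 to 4561512, in replicate 1 and under a w but no c peak, and U5.6 (7.16 ± 0.19) and U6.4 (7.05 ± 0.38) under c but no w peaks. The snoRNA genes ranked highest were AT3G09225 (7.57 ± 0.67) and the adjacent AT3G58193 and AT3G58196, which share 1 peak (7.52 ± 0.36) with the long noncoding RNA gene AT3G09105. AT5G59945 (6.87 ± 0.24), AT5G60963 (6.80 ± 0.18) and AT3G28695 (6.78 ± 0.23) led the tRNA genes. MIR166b (6.28 ± 0.43), MIR5628 (5.84 ± 0.14) and MIR5021 (5.80 ± 0.39) led the microRNA genes. Of the long noncoding RNA genes, AT1G36992 (9.55 ± 0.077), which shares its peak with the protein-coding gene AT1G36990, and AT1G76878 (7.34 ± 0.084) were also among the 3 ranked highest. Of the 4 nuclear rRNA genes of the table, AT2G01010 (1.81 ± 0.022) and AT2G01020 (1.45 ± 0.016) lay under wide peaks of low fold.

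The snoRNA, snRNA, tRNA and long noncoding RNA classes passed the relocation test in each of the 4 lists (adjusted permutation p = 0.0030), and microRNA and rRNA genes passed in none (0.230 to 0.235 for microRNA and 0.833 to 0.949 for rRNA genes in DRIP). On single strands, w and c peaks overlapped 48.4% and 46.3% of snoRNA genes and 28.6% and 21.8% of tRNA genes. The strand difference did not pass in any class (exact McNemar test, adjusted p = 0.21 for tRNA genes). Only 1 rRNA gene differed between strands, too few for this test to pass. With the peak summit required within 100 bp of the gene, the snoRNA value was 3.06-fold and snRNA genes no longer passed on the c strand (1.68-fold, adjusted permutation p = 0.114).

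**Figure D5:**
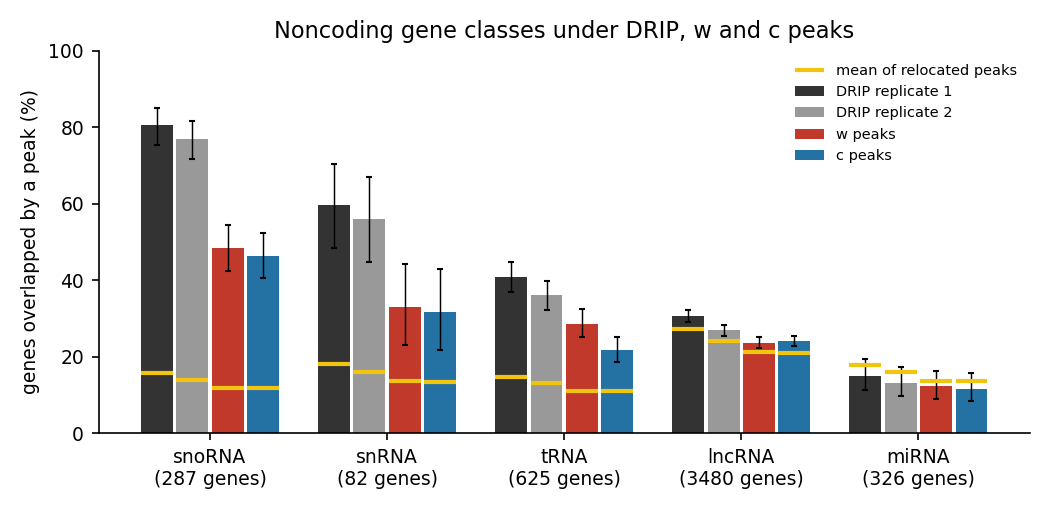
Percent of genes of 5 noncoding classes overlapped by DRIP replicate 1, DRIP replicate 2, w and c peaks (bars, with exact 95% binomial intervals over genes), and the mean after relocation of the peaks (yellow lines). The snoRNA bars, 80.5% and 77.0% in the DRIP replicates, lie farthest above the relocated value.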

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

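The comparison of lower- and higher-coordinate gene ends and its tests, with no other gene within 1 kb and with peaks moved, were chosen only after the data were seen, because the gene table used gives no strand.

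The w and c peaks favoured opposite ends inside isolated protein-coding genes, a difference between these groups of peaks that was itself tested. The log2 ratio of lower-end to higher-end coverage was lower for w than for c by a difference of -2.61 (95% block bootstrap interval -2.80 to -2.42), with the same sign on each of the 5 chromosomes. Both lists are recorded under 1 sample and there is 1 list per strand, so no replicate error exists for this difference.

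Moving w and c peaks back by their median distance from the centres of the DRIP peaks they overlap (4.0 and -4.5 bp) gave -2.59 (-2.78 to -2.40), which decides nothing, because most DRIP peaks overlap peaks of 1 strand only and would be displaced with them. Summits lay off the peak centre in opposite directions, at a median 39.5% of the width for w and 58.5% for c. Of 14215 w peaks with a c peak centre within 1 kb anywhere in the genome, 9058 had the nearest one at the lower coordinate. That was 63.7% (95% block bootstrap interval 62.7 to 64.8). Peaks inside and outside genes were counted together, so this share does not separate gene ends from a general offset. Moving w peaks 150 bp, the length to which DNA was sonicated per the labels and not a measured length, towards lower and c peaks 150 bp towards higher coordinates left -1.63 (-1.82 to -1.46), which argues against a displacement of that length as the whole cause. A part could come from it, since DRIP peaks moved apart by 150 bp each way gave -0.85 in replicate 1 and -0.76 in replicate 2, and displacement by other lengths was not tested. Genes with no other gene within 1 kb gave -2.65 (-2.94 to -2.38). This argues only against signal from genes 500 bp to 1 kb away, because genes with a nearer neighbour were already left out. A candidate explanation is that the hybrid strand follows the orientation of the gene, so that each strand marks the same end of genes of its orientation. Over 1496 genes of 3 kb or longer the log2 ratio of the odds ratios for the opposite pairings of ends was 0.42 (-0.19 to 1.06). This ratio cannot decide, because the candidate would make both pairings rare in the same gene. A c peak at the lower end and a w peak at the higher end occurred together in 186 genes. Their odds ratio was 1.07 (95% interval 0.86 to 1.34), and that of the reverse pairing 0.80 (0.54 to 1.16). These values argue against a strict rule of 1 strand per gene, and a looser tendency stays open. The gene strand itself was not used here.

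The w and c peaks overlapped less than chance. Removal of the signal of both strands by the peak calling would leave strong DRIP peaks with neither strand. Among DRIP peaks found in both replicates 1.36% of the lowest fold quartile had neither a w nor a c peak (95% Wilson interval 1.15 to 1.61) and 0 of 9101 in the highest, which allows up to 0.0422%. The w and c lists are recorded under replicate 1, whose peaks were counted, so a strong peak was likely to carry 1 of them in any case. Loss of the weaker strand alone would leave the peak of the stronger strand and was not tested. Whether the calling removed opposite-strand signal therefore stays open, and no biological explanation was tested.

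The excess of snoRNA genes under DRIP peaks was not carried by protein-coding host genes alone. The 203 snoRNA genes outside protein-coding genes were overlapped 5.73-fold ± 0.38 over relocation (SD, n = 2, two-sided permutation p = 0.0020, the smallest possible). Noncoding host genes were not set apart. The excess was not due only to clusters being counted several times, since 142 clusters counted once were overlapped 3.79-fold ± 0.16 over relocation. The design has no group that tests a biological explanation.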

How the results depend on the processing

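Relocation within 100 kb for genome features, 1 kb on either side for gene lists, the coordinate-named ends and isolation by 1 kb were chosen only after the data were seen. Over 60 results, 315 of 345 alternative values kept their direction and side of the threshold, 12 no longer passed, 6 newly passed and 12 reversed. The causes were not tested.

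For peaks in the upper 50% by fold, pseudogenes no longer passed (w 1.04-fold, c 1.03-fold), long noncoding RNA genes newly passed (w 0.877, c 0.808), rRNA genes were at 0-fold (DRIP, w and c), and list ratios over matched lists reversed for R-loop factors (0.638, 2 of 6 genes) and NLR genes (0.990, 8 of 14). With a q-value 10 times stricter long noncoding RNA genes newly passed for c (0.897). By summit these genes no longer passed for DRIP (0.971) and reversed for w (1.03), rRNA genes reversed (0.773) and snRNA genes no longer passed for c (1.68). Without pericentromeres long noncoding RNA genes newly passed (w 0.863, c 0.831). The log2 ratio of gene ends to middle was 0.16 over all protein-coding genes and -0.18 with 250 bp windows.

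Heat shock genes no longer passed by summit (1.82), without length matching (1.53) and with 1 kb on either side (1.38). Leaving out 1 replicate gave 1.70 to 1.72, and the result was lost without replicate 1. Developmental regulators reversed with 1 kb (0.987) and without replicate 2 (range 0.982 to 1.06). Histone genes reversed by summit (0.946) and without matching (0.721) and had 12 of 16 genes with a peak, in place of 7, with 1 kb on either side, and flowering genes without matching (1.1). On the c strand photosynthesis genes no longer passed by summit (1.61) and with 1 kb (1.34), nor did housekeeping genes (1.55 and 1.27).

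Of 111 named genes, 94 had a DRIP peak in both replicates, 94 with the stricter q-value and 90 in the upper 50%. No paired analysis was possible because only the DRIP samples have values here, and the RNase H samples with the same replicate numbers were not analysed here. Orientation to genes, sequence skew, organelle genomes and 1 kb upstream were not run, and the replicate overlap needs both replicates. Unknown depth limits what an absent peak shows.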

Other observations

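All tests of tRNA runs, gene families and pericentromeric regions were chosen only after the data were seen, and they are given as values without explanation.

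Transfer RNA genes in tandem runs carried w peaks and no c peaks. In 6 runs of at least 5 tRNA genes with gaps under 1 kb, holding 118 genes, 41 genes carried a w peak and 0 a c peak. The largest run, 81 genes on chromosome 1 from AT1G56730 to AT1G57530, had 18 genes with a w peak. Outside the runs 27.2% of 507 tRNA genes carried a w and 26.8% a c peak (exact McNemar p = 0.948). Neighbouring genes of a run are not independent, so no p is given for the runs.

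Gene families were defined by symbol stem alone, with at least 15 members, so genes of a stem need not be related. Families differed from length-matched lists in 11 of 90 cases, 9 above and 2 below, by a test that takes members as independent. Members of some families are clustered: the 58 UGT genes lie in 36 different 50 kb bins, the 40 BGLU genes in 30 and the 80 LCR genes in 53, so no p is given. UDP-glycosyltransferase genes (UGT) had DRIP peaks in both replicates in 54 of 58 cases against 62.0% matched, and ERF transcription factor genes in 21 of 23 against 53.0%. EMB genes had 96 of 112 against 69.4%, and AGP, KCS, CPK, FLA, IAA and HSP genes also lay above. The HSP stem shares members with the fixed heat shock list, such as HSP101, HSP70 and HSP18.2, so it is no separate result. Beta-glucosidase genes (BGLU) had 14 of 40 against 71.7%, and the LCR genes of small secreted cysteine-rich proteins 10 of 80 against 31.5%. The IAA stem (21 of 24) leaves out SHY2 and ATAUX2-11, which carry no DRIP peak, and AXR3, which has one in replicate 1 only. The fixed Aux/IAA list did not pass.

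Pericentromeric regions, set by low gene content and 25 Mb in all, were covered 1.16-fold ± 0.022 as much as the arms (SD, n = 2). On chromosome 1 the ratio was 1.07 and 1.01 in the DRIP replicates, 1.09 for w and 0.98 for c peaks. Intergenic DNA was covered 9.69% ± 1.03 there and 2.31% ± 0.29 in the arms, and gene flanks 12.1% ± 1.16 and 6.33% ± 0.33. Pseudogenes were covered 16.7% ± 1.6 and 16.3% ± 1.55, and small RNA genes less in the pericentromeric regions, 26.7% ± 1.39 against 34.9% ± 0.98. The widest DRIP peak, at chromosome 4, 3055931 to 3061253 in replicate 1 (5323 bp, fold 2.13), spans AT4G05175, AT4G05185, AT4G05195 and AT4G06477, and replicate 2 has a peak of 5332 bp there.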
